A study of Mus with 9 samples.

How the data were processed

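Gene expression was measured by bulk RNA sequencing in 9 mouse libraries described as left atrium. They fall into 3 groups of 3 by their labels: sham surgery with vehicle (Sham 1 to 3), myocardial infarction with vehicle (titled MI 2, MI 3 and MI 4), and myocardial infarction with artesunate, an antimalarial artemisinin derivative (MI_ART 1 to 3). Infarction was made in male C57BL/6J mice by tying off the left anterior descending coronary artery for good. The labels conflict on the artesunate dose. The treatment protocol gives 25 mg/kg daily from surgery, whereas the series design text gives 10 mg/kg every other day, beginning 2 days before surgery and ending on day 7. They also call the animals mice in some places and rats in others, name a further group that has no library, and describe different RNA extractions. The day of tissue harvest is not stated. The tissue field reads atria, and the series design text reads left atrium. Libraries were made from 1.3 µg of RNA with a SMARTer mRNA kit. Nothing beyond the sample labels says that each library came from a separate animal, so the p-values measure the spread between these samples.

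The deposited values are raw counts of reads per Ensembl gene, with no normalization. The submitters' notes name HISAT (version not given), featureCounts 1.5.0-p3, DESeq 1.8.3 and the GRCm38 build. The strand setting, the rule for reads that map to several places and any filter are not given in the sources used here. Where an annotated gene overlaps another, its count is therefore uncertain. The table holds 55421 genes and 9 columns, all used. The 9 per-sample files equal the table at a tolerance of 0. Total counts per library ranged from 68046341 to 83685313. At that depth a floor of 3 counts per library corresponded to 0.0322 to 0.0592 CPM (the usual read count unit, here over the TMM-scaled library size). A group with no counts was set at this floor, and the resulting bound covers counting error only. Gene symbols were matched to a RefSeq gene table for 17846 of the tested genes (92.3%), and 119 symbols occur more than once in the table. No genome sequence was at hand.

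Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 3 groups, which left 19326 tested genes. Libraries were scaled by the trimmed mean of M values (TMM), and all 9 libraries were fitted together with 1 mean per group. The common dispersion was 0.150 (biological coefficient of variation 0.388), with 3.80 prior degrees of freedom. Quasi-likelihood F tests compared MI with Sham, MI_ART with MI and MI_ART with Sham, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene given without another tool's name comes from this edgeR fit. Fold changes are given with their standard error (SE), and group means in CPM with the standard deviation (SD) of 3 libraries. Single values per library were compared by two-sided exact permutation tests, whose smallest p for 3 against 3 is 0.1.

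A set of 58 gene lists with 1023 distinct genes was fixed for heart tissue, infarction, artesunate and other cell types, of which 42 genes were not tested for low counts. The 57 lists with at least 4 measured members were tested with camera (limma 3.58.1) on voom values at a preset correlation between genes of 0.01, then with an estimated correlation, and with fry. Camera compares a list with all other genes. Fry asks whether the members move on balance in 1 direction, or, in its mixed form, in either direction. Member counts are given at the adjustment over all tested genes and adjusted over the list alone. The genes named are a fixed panel of 21 genes, chosen whatever their result, and in each comparison the 10 called genes with the highest and the 10 with the lowest fold changes. The latter needed a mean of at least 1 CPM in 1 group and no overlap between the libraries of both groups, and left out predicted genes, pseudogenes and immunoglobulin or T cell receptor segments. To these were added the 4 members with the smallest p of each described list (the 2 with the highest expression where none passed), genes called in opposite directions, and, where fewer than 5 genes passed in a direction, the 5 with the smallest unadjusted p. A few genes that this rule chose are not reported here, so counts over the panel and the lists include genes that are not named. Lists, tests, comparisons, this naming rule and the alternatives were set before the data were examined, except where stated.

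Because MI is in both MI versus Sham and MI_ART versus MI, opposite calls and the covariance of fold changes were set against 30 simulations of unchanged groups with the same shared libraries. The fit was tested on simulated data with changes of known size added. A 4-fold change was recovered for 58.3% of genes in MI versus Sham, 67.7% in MI_ART versus MI and 67.2% in MI_ART versus Sham, and a 2-fold change for 8.70%, 8.22% and 12.7%. Of 19096 unchanged genes in MI_ART versus MI, edgeR called 7 and DESeq2 called 50.

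Alternatives were other scalings (RLE, upper-quartile), DESeq2 1.42.0, limma-voom, no filter, a filter of at least 5 CPM in at least 3 libraries, each pair of groups fitted alone, the title number as a replicate block, a fold change minimum and each library left out in turn. After the data were seen, 3 more were added: total counts with no scaling, a covariate for the level of atrial transcripts (the mean log2 CPM of Myl7, Myl4, Sln and Mybphl), and MI 4 and MI_ART 3 left out together. On the covariate MI_ART 3 stands far apart (Myl7 at 1.96 CPM, against 168 to 989 elsewhere), so it mainly sets that library aside. In MI_ART versus Sham it gave 1800 higher and 705 lower genes, against 1797 and 659 without MI_ART 3. TMM factors ranged from 0.624 to 0.744 in Sham, from 1.19 to 1.28 in MI and from 1.14 to 1.17 in MI_ART, so leaving such factors out shifts fold changes against Sham. With total counts the median log2 fold change of all genes was 0.88 in MI versus Sham, 0.75 in MI_ART versus Sham and -0.11 in MI_ART versus MI, against 0.04 for MI versus Sham with TMM. RLE and upper-quartile factors also gave 0.04 for MI versus Sham.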

Results

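Messenger RNA was counted in samples described as left atrium from sham-operated mice given vehicle (Sham), infarcted mice given vehicle (MI) and infarcted mice given artesunate (MI_ART), with 3 libraries per group. Total counts were 76147961, 68046341 and 83685313 in Sham 1 to 3, 73621277, 73533537 and 72376936 in MI 2, MI 3 and MI 4, and 69730075, 69974836 and 69363844 in MI_ART 1 to 3. The series title concerns atrial fibrillation after infarction. The comparisons ask what infarction changes in these samples, what artesunate changes after infarction, and what still differs from sham surgery with artesunate.

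Transcripts of ventricular and atrial muscle were both present, in proportions that varied within groups. Myl2, the ventricular regulatory myosin light chain, exceeded Myl7, its atrial counterpart, in 8 of 9 libraries, with MI 4 as the exception. Myl2 over Myl7 was 3.64, 17.7 and 6.57 in Sham 1 to 3, 1.87, 2.36 and 0.460 in MI 2, MI 3 and MI 4, and 5.45, 1.22 and 784 in MI_ART 1 to 3. In MI_ART 3 Myl7 was at 1.96 CPM, against 173 in MI_ART 1 and 803 in MI_ART 2. Myl4, the atrial essential light chain, was at 6.21 CPM in MI_ART 3, against 268 and 1474 in the other MI_ART libraries. MI 4 stood apart from the other MI libraries. Its counts differed from those of MI 2 and MI 3 with a chi-square per gene of 585 and 472, against 69.0 to 132 for every other pair within a group, and its second principal component was 107, against -43.9 to 25.0 elsewhere. It held the lowest Ttn (titin) among the 9 libraries at 178 CPM and the highest Rplp0, a ribosomal protein, at 1977 CPM, against 670 to 1006 elsewhere. Differences between groups in muscle genes stand beside these differences within groups.

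**Figure D1:**
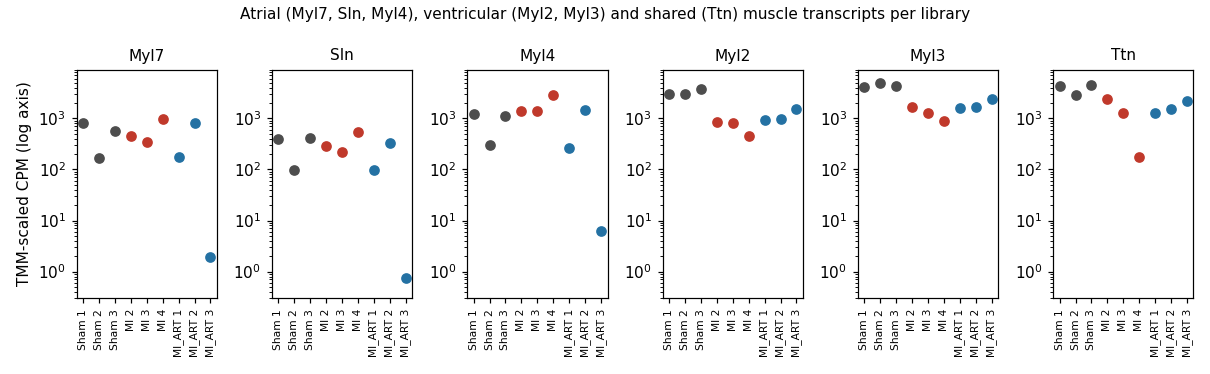
Each panel plots 1 transcript in CPM on a log axis, with 1 point per library, for atrial (Myl7, Sln, Myl4), ventricular (Myl2, Myl3) and shared (Ttn) muscle transcripts. MI_ART 3 has 1.96 CPM of Myl7 and 0.740 of Sln, and MI 4 has 178 CPM of Ttn.

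After infarction, extracellular matrix, inflammatory and cell cycle genes were higher than in Sham, and genes of mitochondrial energy metabolism were lower. Ventricular transcripts were present in these samples, so the changes are not shown to be atrial. MI_ART 3, with Myl7 at 1.96 CPM, also stood above Sham, by a median log2 of 1.89 in matrix, 4.095 in cell cycle and 3.12 in macrophage genes. Which chamber the changes came from was not tested. Col3a1 (collagen III, chromosome 1, 45311538 to 45349706) rose from 368 ± 67.3 to 4086 ± 338 CPM (SD, n = 3 each), 11.1-fold. Hmox1, the haem-degrading enzyme haem oxygenase 1 (chromosome 8, 75093618 to 75100593), rose from 10.9 ± 0.539 to 298 ± 72.5 CPM, 27.3-fold. Cthrc1 (chromosome 15, 39076932 to 39087121), made by activated fibroblasts, rose from 0.513 ± 0.254 to 99.4 ± 19.0 CPM, 193-fold. Atp2a2, the calcium pump of the sarcoplasmic reticulum (chromosome 5, 122453513 to 122502225), fell 4.01-fold from 12415 ± 1095 to 3097 ± 1691 CPM. Of 19326 tested genes, 3631 were higher and 2768 lower in MI than in Sham (33.1%), and 9457 (48.9%) had no overlap between the libraries of both groups, where chance gives 10%. Of the calls 56.7% were higher, against 93.7% (9528 higher, 644 lower) with total counts.

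Of 30 measured genes for fibrillar collagen and matrix, 27 rose and 1 fell (28 and 1 adjusted over the list alone), with a median log2 fold change of 2.41. The camera test gave an adjusted p = 2.13e-19, and adjusted p = 0.116 with an estimated correlation. Col1a1 (collagen I) rose from 38.4 ± 6.97 to 877 ± 316 CPM, and Lox, which crosslinks collagen, rose 32.7-fold. Col12a1 and Col5a2 rose 25.6-fold and 9.83-fold. Of 16 genes for activated fibroblasts and myofibroblasts, 13 rose (13 adjusted over the list alone), with a median of 2.16 (camera adjusted p = 6.69e-09, and adjusted p = 0.116 with an estimated correlation). They include Tnc (tenascin C), 122-fold higher, Fn1 (fibronectin), 21.9-fold higher, and Postn (periostin), 10.3-fold higher with an adjusted p of 8.76e-05. Of 22 matrix proteases and their inhibitors, 16 rose and 1 fell (17 and 1 adjusted over the list alone), among them Timp1 (82.4-fold) and Mmp14 (8.10-fold). That list's median was 2.32, with a camera adjusted p = 2.68e-07 and adjusted p = 0.123 with an estimated correlation. Of 22 TGF-beta signalling genes, 14 rose (15 adjusted over the list alone), with a camera adjusted p = 1.30e-05 and adjusted p = 0.116 with an estimated correlation. Tgfb1 rose 4.89-fold (log2 2.29, SE 0.39), and Ltbp2 (log2 3.58), Thbs1 and Ccn2 also rose, the latter pair 11.4-fold and 4.78-fold.

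Inflammatory genes and markers of myeloid cells were higher together. Of 30 cytokines and chemokines, 27 rose and 1 fell (28 and 1 adjusted over the list alone), with a median log2 fold change of 3.97, or 3.27 with genes absent from Sham set at their bound. The camera adjusted p was 6.79e-11, and adjusted p = 0.147 with an estimated correlation. The monocyte attractant Ccl2 rose from 1.69 ± 0.515 to 40.1 ± 14.9 CPM, Spp1 (osteopontin) 326-fold, Il1b 34.4-fold, and Il6 129-fold from 4 counts in all of Sham. Of 20 macrophage and monocyte genes, 17 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 2.84 (camera adjusted p = 1.97e-10, and adjusted p = 0.147 with an estimated correlation). Ccr2 rose 13.6-fold, Trem2 23.4-fold and Cd68 13.8-fold. Of 11 neutrophil genes, 10 rose (11 adjusted over the list alone), with a median of 5.90, or 5.46 at the bound (camera adjusted p = 0.000892, and adjusted p = 0.332 with an estimated correlation). Csf3r rose 37.1-fold and S100a9 72.4-fold, and the neutrophil collagenase Mmp8 was at least 37.5-fold higher. Of 18 genes of the NLRP3 inflammasome and pyroptosis, 13 rose and 1 fell (14 and 1 adjusted over the list alone), with a camera adjusted p = 3.67e-05 and adjusted p = 0.147 with an estimated correlation. Nlrp3 rose 8.20-fold, Casp8 3.46-fold and Casp1 2.14-fold.

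Of 30 cell cycle genes, 27 rose (28 adjusted over the list alone), with a median log2 fold change of 4.31 (camera adjusted p = 2.19e-17, and adjusted p = 0.147 with an estimated correlation). Ccnb1 (cyclin B1) rose from 0.292 ± 0.109 to 19.3 ± 4.11 CPM, and Cdk1 from 0.952 ± 0.120 to 33.9 ± 8.79 CPM. Of 25 stress and fetal cardiac genes, 11 rose (13 rose and 1 fell adjusted over the list alone), with a camera adjusted p = 0.000632 and adjusted p = 0.147 with an estimated correlation. Nppb (B-type natriuretic peptide, chromosome 4, 147985786 to 147987205) rose 7.05-fold (log2 2.82, SE 0.38) to 480 ± 108 CPM, and Nmrk2, which makes NAD precursors, 61.8-fold. Nppa (atrial natriuretic peptide) had a log2 fold change of 2.12 (SE 0.74) with an adjusted p of 0.0515, and it passed in 9 of 20 alternatives (adjusted p from 0.00765 to 0.260), among them without MI_ART 2 (0.0133) and without MI_ART 3 (0.0332).

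Of 49 nuclear oxidative phosphorylation genes, 48 fell (48 adjusted over the list alone), with a median log2 fold change of -1.20 (camera adjusted p = 1.01e-22, and adjusted p = 0.147 with an estimated correlation). Cox7a1, a muscle subunit of cytochrome c oxidase, fell 5.26-fold and Ndufa9, a complex I subunit, 2.63-fold. All 13 mitochondrially encoded transcripts fell (13 adjusted over the list alone), with a median of -2.09 (camera adjusted p = 5.24e-12, and adjusted p = 0.147 with an estimated correlation). They include mt-Nd5, which fell 5.10-fold. Of 33 fatty acid oxidation genes, 28 fell (29 adjusted over the list alone), with a median of -1.71 (camera adjusted p = 1.03e-15, and adjusted p = 0.147 with an estimated correlation). The thiolase Acaa2 fell 3.69-fold and Mlycd, the malonyl-CoA decarboxylase, 3.03-fold. Of 21 tricarboxylic acid cycle genes, 19 fell (20 adjusted over the list alone), with a median of -1.43 (camera adjusted p = 1.19e-11, and adjusted p = 0.147 with an estimated correlation). Suclg1, a subunit of succinyl-CoA ligase, fell 2.51-fold. With total counts these 4 medians stayed below 0, at -0.35, -1.23, -0.86 and -0.58, but fewer members passed: 16 oxidative phosphorylation genes, 13 mitochondrially encoded transcripts, 23 fatty acid oxidation genes (with 1 higher) and 12 tricarboxylic acid cycle genes were lower. Mitochondrial genes took 40.1% ± 2.80 of all counts in Sham, 17.3% ± 4.21 in MI and 24.0% ± 1.33 in MI_ART (SD, n = 3), and each pair of groups gave an exact permutation p of 0.1, the smallest that 3 against 3 can give. Nuclear copies of mt-Co3, mt-Co2 and mt-Atp6 held 91.7% to 104% of the counts of these genes, so the same reads may have been counted more than once, and the shares depend on how such reads were counted. Marker lists of cell types rich in mitochondria fell in MI as well: that of ventricular muscle by a median log2 of -1.39, and that of brown adipocytes by -1.67 (-0.83 with total counts), with 4 of 9 lower and 1 higher (4 and 1 adjusted over the list alone, camera adjusted p = 0.00398, and adjusted p = 0.147 with an estimated correlation). The brown adipocyte list includes Cox7a1 and Fabp3, which heart muscle also expresses. Whether the cells changed or their shares did was not tested for the energy genes.

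Electrical and contractile genes were lower in part, and the medians of several of their lists turned above 0 with total counts. With total counts the median of all genes was itself 0.88, and mitochondrial genes took 40.1% of counts in Sham against 17.3% in MI. How much of the turn these shares explain was not tested. RLE and upper-quartile factors kept these medians near their TMM values, at -0.797 and -0.801 for atrial ion channels. Of 38 atrial ion channel genes, 18 fell and 4 rose (20 and 4 adjusted over the list alone), with a median log2 fold change of -0.81 that turned to 0.04 with total counts, where 5 were lower and 7 higher (camera adjusted p = 0.000179, and adjusted p = 0.233 with an estimated correlation). Kcnip2 and Kcnd2, subunits of the transient outward potassium current, fell 5.72-fold and 6.16-fold. Of 26 calcium handling genes, 8 fell and 3 rose (10 and 3 adjusted over the list alone), with a median of -0.25 that turned to 0.60 with total counts, where 4 were lower and 8 higher (camera adjusted p = 0.0443, and adjusted p = 0.200 with an estimated correlation). The calcium handling call was lost without Sham 1 (0.0522) or Sham 2 (0.0528). Hrc fell 6.20-fold and Pln (phospholamban) 4.57-fold. Of 25 sarcomere genes, 15 fell and 1 rose (16 and 2 adjusted over the list alone), with a median of -0.82 that turned to 0.02 with total counts, where 4 were lower and 3 higher (camera adjusted p = 1.31e-05, and adjusted p = 0.207 with an estimated correlation). Tcap fell 3.91-fold, and Myh6, the fast myosin heavy chain, 2.68-fold. Of 20 gap junction and intercalated disc genes, 7 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.48 that turned to 0.35 with total counts, where 1 was lower and 5 higher (camera adjusted p = 0.00398, and adjusted p = 0.361 with an estimated correlation). Their median difference from Sham was -0.24 in MI 2, -0.37 in MI 3 and -1.47 in MI 4, and that of the calcium handling genes -0.25, -0.20 and -0.61. The desmosome genes Dsg2 and Dsp fell 3.35-fold and 2.80-fold, and with total counts Dsp did not pass (log2 -0.67, adjusted p = 0.0989). Of 12 ventricular muscle genes, 10 fell (11 adjusted over the list alone), with a median of -1.39, and Myl2 fell 4.60-fold, whereas with total counts 5 were lower and 1 higher with a median of -0.56 (camera adjusted p = 9.94e-06, and adjusted p = 0.147 with an estimated correlation). Of 18 atrial muscle genes, 5 fell (5 lower and 2 higher adjusted over the list alone), and the list's median of -0.35, called lower by camera (adjusted p = 0.0414, and adjusted p = 0.518 with an estimated correlation), stood against a mean of 0.19 and turned to 0.49 with total counts. The atrial cardiomyocyte call was lost without Sham 1 (0.108), MI 3 (0.0648) or MI_ART 3 (0.0700). A control list of 4 male-specific transcripts was also called lower (camera adjusted p = 0.0450, and adjusted p = 0.437 with an estimated correlation). Its median of -0.72 turned to 0.13 with total counts. Its median difference from Sham was -0.46 in MI 2, -0.50 in MI 3 and -1.64 in MI 4.

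Of the 21 panel genes 11 were higher and 4 lower in MI, and the calls of 3 of the 4 lower genes depended on single libraries. Atp2a2 passed with each library left out. Ryr2, the calcium release channel, had a log2 fold change of -1.37 (SE 0.40, adjusted p = 0.0260) and did not pass without Sham 1, Sham 3 or MI 3, with adjusted p from 0.00485 to 0.0799 over the 9 libraries left out in turn, nor with total counts (-0.53, adjusted p = 0.267). Cacna1c, the L-type calcium channel, had -1.44 (adjusted p = 0.0488) and among the single libraries left out passed only without MI 2 or MI 4 (0.0122 to 0.164), and did not with total counts (-0.64). Kcna5, an atrial potassium channel, had -0.81 (adjusted p = 0.0498), which turned to 0.05 with total counts. Among the single libraries left out Kcna5 passed only without MI 3 or MI_ART 3 (0.0300 to 0.136). Gja1 (connexin 43, adjusted p = 0.126), Gja5 (connexin 40, 0.662) and Kcnj3 (0.0781) did not pass. Gpx4, the lipid peroxidase that restrains ferroptosis, had -0.37 (adjusted p = 0.214), which turned to 0.49 with total counts. Without MI 4 Gpx4 passed at -0.64 (adjusted p = 0.00613, with up to 0.504 over the 9 libraries left out in turn).

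Among the called genes with the highest fold changes, 9 had no counts in Sham: Marco (a macrophage scavenger receptor) was at least 228-fold higher, Depdc1a at least 149-fold, Apoc2 at least 138-fold, Crct1 at least 122-fold, Sirpb1b at least 90.5-fold, Steap1 at least 72.5-fold, Eme1 at least 52.5-fold, Ticrr at least 47.6-fold and Cfi (complement factor I) at least 43.2-fold. Sprr1a had 18 counts in Sham and 231 ± 153 CPM in MI. At the other end, Cyp1a1 had no counts in MI and was at least 53.1-fold lower. Inmt fell 36.5-fold, Kcnv2 19.2-fold, Cngb3 17.9-fold and Acsm5 17.6-fold. Helt, Clec18a, Plk5 and Aldh3b3, all under 2 CPM in Sham, fell 24.6-fold, 18.1-fold, 17.2-fold and 35.2-fold. The Aldh3b3 call was lost without Sham 1 or MI 3 (adjusted p from 0.00699 to 0.0642 over the 9 libraries left out in turn), and Sirpb1b has close copies in the genome.

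**Figure D2:**
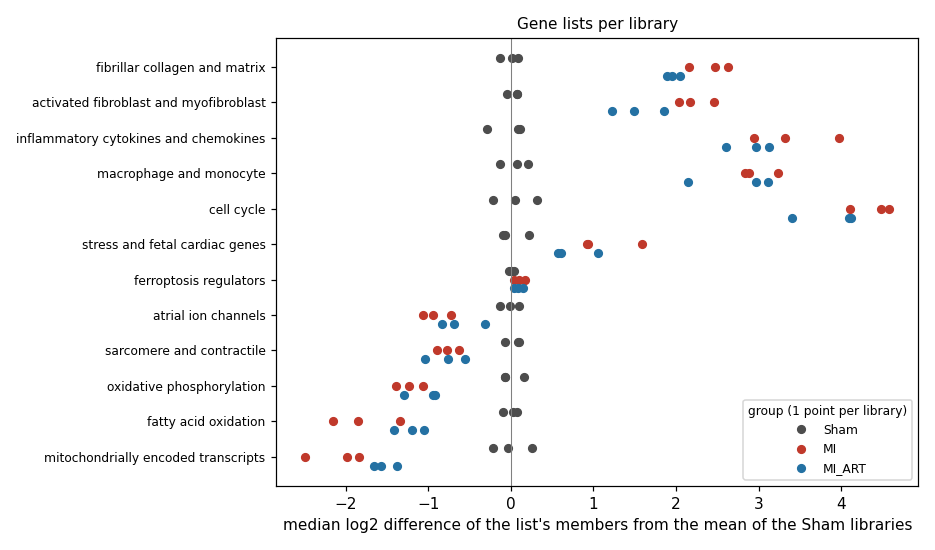
Each point is the median over a list's members of the log2 difference of 1 library from the mean of the Sham libraries, for 12 lists. All 6 infarcted libraries lie above Sham for matrix, fibroblast, cytokine, macrophage and cell cycle genes and below it for mitochondrial and fatty acid oxidation genes, while the medians of atrial ion channels and sarcomere genes in MI versus Sham turn from below to above 0 with total counts (0.04 and 0.02).

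With artesunate after infarction, 2 genes passed the test against vehicle, both lower. Slc39a9, a zinc transporter of the Golgi (chromosome 12, 80643883 to 80683342), fell from 34.2 ± 5.33 to 5.87 ± 1.03 CPM (SD, n = 3 each), 5.83-fold (log2 -2.54, SE 0.19, adjusted p = 0.00277). Its level in Sham was 29.9, 30.2 and 31.2 CPM, and MI did not differ from Sham (log2 0.17, adjusted p = 0.513). Tnnt3, the fast skeletal troponin T (chromosome 7, 142498771 to 142516213), fell from 39.4 ± 21.6 to 2.17 ± 0.783 CPM, 18.2-fold (log2 -4.18, SE 0.46, adjusted p = 0.0447), and had risen in MI against Sham (log2 5.98, adjusted p = 9.03e-05). Both loci overlap another gene in part: Erh beside Slc39a9 (log2 -0.45, adjusted p = 0.716) and Prr33 beside Tnnt3 (0.25, adjusted p = 0.768).

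No gene was higher by edgeR among 19326, 1346 genes had an unadjusted p under 0.05, DESeq2 called 45 higher and 40 lower, and limma-voom called 0 and 1. In 2686 genes (13.9%) the libraries of both groups did not overlap, where chance gives 10%. The number of calls changed with single libraries. Without MI 2, 1 gene was higher (Kcnv2, log2 2.91, adjusted p = 0.0276) and 2 were lower. Without MI 3, 3 genes were lower: Slc39a9, Rab11b (log2 -1.50) and the predicted gene Gm21982 (-4.90). Without MI_ART 2, 0 genes passed. Without MI_ART 1, 2 genes were lower, and 1 was lower without each of Sham 1, Sham 2, Sham 3, MI 4 and MI_ART 3. Kcnv2, Rab11b and Gm21982 were named after their values were seen. Slc39a9 kept its call in 8 of the 9 fits with 1 library left out, with log2 fold changes from -2.69 to -2.45. Slc39a9 lost its call without MI_ART 2 (log2 -2.49, adjusted p = 0.0533), within a range of 1.21e-28 to 0.110 over the alternatives. Tnnt3 kept its call without MI 2 alone among the single libraries (0.0248 to 0.293), with log2 fold changes from -4.47 to -3.66.

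**Figure D3:**
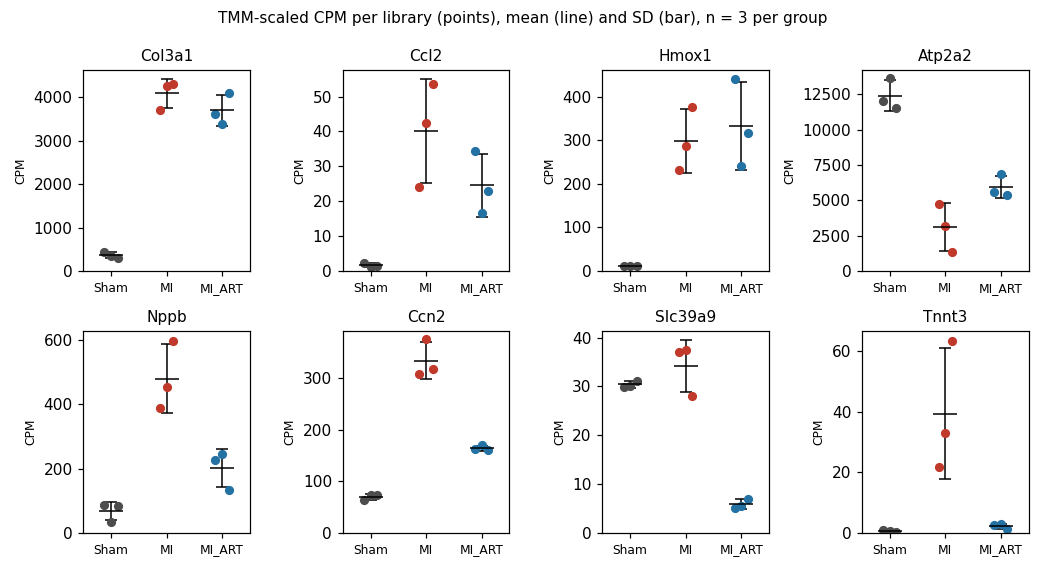
CPM per library (points), mean (line) and SD (bar, n = 3) for 8 named genes. Slc39a9 lies between 5.08 and 7.03 CPM in the MI_ART libraries and between 28.1 and 37.5 in the other 6, and Col3a1 and Hmox1 stand at similar levels in MI and MI_ART.

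None of the 21 panel genes passed in MI_ART versus MI (smallest adjusted p = 0.656). Col3a1 was at 3693 ± 366 CPM with artesunate against 4086 ± 338 without (log2 -0.15, SE 0.18), and Hmox1 at 333 ± 101 against 298 ± 72.5 (log2 0.16, SE 0.25). Nppb was at 202 ± 59.6 against 480 ± 108 CPM (log2 -1.25, SE 0.36, adjusted p = 0.656), and Atp2a2 at 5957 ± 777 against 3097 ± 1691 CPM (log2 0.94, SE 0.36, adjusted p = 0.709). Log2 fold changes of Tgfb1 (-0.88), Il6 (-0.93), Ccl2 (-0.71) and Nlrp3 (-0.70) had adjusted p of 0.709, 0.752, 0.730 and 0.724, and that of Gpx4 was -0.10 (0.926). The genes of smallest unadjusted p that did not pass were, on the lower side, Nrg1 (neuregulin 1, log2 -1.99, adjusted p = 0.196), Ccn2 (connective tissue growth factor, -1.03, 0.237), Edn1 (endothelin 1, -1.44, 0.410), Tnni2 (fast skeletal troponin I, -3.55, 0.455) and Ube2g2 (-1.06, 0.455). On the higher side they were Ccnd3 (1.05), Wif1 (1.65), Rab17 (2.82) and Lingo3 (1.58), all with an adjusted p of 0.456, and Galnt15 (0.88, 0.490). All 10 passed with DESeq2 (adjusted p from 2.87e-08 for Nrg1 to 0.00487 for Galnt15) and with no other alternative. Ccn2 was at 334 ± 35.7 CPM in MI and 164 ± 5.08 in MI_ART.

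As lists, 8 were higher and 11 lower by camera out of 57, with 0 of these 19 calls at an estimated correlation and 0 by fry in 1 direction (7 lists in its mixed form). Activated fibroblast genes had a median log2 fold change of -0.61, with 0 of 16 called over all genes and 6 lower adjusted over the list alone (camera adjusted p = 2.33e-06, and adjusted p = 0.284 with an estimated correlation). Matrix genes had a median of -0.38, with 0 of 30 called over all genes and 3 lower adjusted over the list alone (camera adjusted p = 8.80e-09, and adjusted p = 0.284 with an estimated correlation). Their most expressed members Sparc and Fn1 had log2 fold changes of -0.51 and -0.43 (adjusted p = 0.709 and 0.753). Stress and fetal cardiac genes had a median of -0.34, with 2 lower adjusted over the list alone (camera adjusted p = 2.28e-05, and adjusted p = 0.284 with an estimated correlation). The TGF-beta list had -0.41, with 1 lower adjusted over the list alone (camera adjusted p = 0.000647, and adjusted p = 0.284 with an estimated correlation). Cell cycle genes had -0.45, with 0 adjusted over the list alone (camera adjusted p = 4.30e-10, and adjusted p = 0.522 with an estimated correlation). The list of inflammatory cytokines and chemokines had -0.39, with 0 adjusted over the list alone (camera adjusted p = 0.00102, and adjusted p = 0.579 with an estimated correlation), and lost the camera call without MI 4 (0.0508) or MI_ART 2 (0.205).

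Fatty acid oxidation genes had a median log2 fold change of 0.48 in MI_ART versus MI, with 0 of 33 called, also adjusted over the list alone (camera adjusted p = 2.70e-10, and adjusted p = 0.514 with an estimated correlation). Mitochondrially encoded transcripts had 0.54 (camera adjusted p = 1.02e-08, and adjusted p = 0.514 with an estimated correlation), and their share of all counts differed by 6.66 points with no overlap between the groups, and by 4.29 points without MI 4. mt-Co1 had a log2 fold change of 0.60 (adjusted p = 0.718), and Fabp3, a fatty acid carrier of heart muscle, 0.46 (0.732). The atrial ion channels had a median of 0.30 (camera adjusted p = 0.00258, adjusted p = 0.535 with an estimated correlation, and 0.262 without MI_ART 2), and Abcc9, a subunit of the ATP-sensitive potassium channel, had 0.98 (adjusted p = 0.709). Ventricular muscle genes, which among the infarcted libraries stood lowest in MI 4 (median log2 difference from Sham -2.05), had 0.58 (camera adjusted p = 4.28e-05, and adjusted p = 0.514 with an estimated correlation). The macrophage and monocyte genes (median -0.05, camera adjusted p = 0.220, but 0.0169 without MI_ART 1 and 0.0103 without MI_ART 3), inflammasome genes (-0.13, 0.270) and ferroptosis regulators (-0.03, 0.589) were not called.

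The MI_ART samples, of which MI_ART 3 held hardly any atrial transcripts, also had higher matrix, inflammatory and cell cycle genes and lower genes of mitochondrial energy metabolism than Sham. Col3a1 was 10.0-fold higher than in Sham (log2 3.33, SE 0.20, n = 3 each), Col1a1 17.0-fold, Hmox1 30.5-fold and Ccl2 14.5-fold. Nppb was 2.98-fold higher (log2 1.57, adjusted p = 0.0144) and Atp2a2 had a log2 fold change of -1.06 (SE 0.37) with an adjusted p of 0.0682. Of 30 matrix genes 27 rose and 1 fell (27 and 1 adjusted over the list alone), with a median of 1.87 (camera adjusted p = 1.71e-22, and adjusted p = 0.0838 with an estimated correlation). Of 30 cell cycle genes 27 rose (27 adjusted over the list alone), with a median of 3.87 (camera adjusted p = 6.38e-20, and adjusted p = 0.139 with an estimated correlation). Of 20 macrophage genes 17 rose (17 adjusted over the list alone), and of 30 cytokines and chemokines 25 rose (27 higher and 1 lower adjusted over the list alone), with camera adjusted p of 2.01e-13 and 1.09e-12 and, for each, adjusted p = 0.138 with an estimated correlation. Of 49 oxidative phosphorylation genes 48 fell (48 adjusted over the list alone), with a median of -1.06 (camera adjusted p = 3.53e-27, and adjusted p = 0.138 with an estimated correlation), and of 33 fatty acid oxidation genes 24 fell (26 adjusted over the list alone), with a median of -1.21 (camera adjusted p = 9.13e-15, and adjusted p = 0.156 with an estimated correlation). With total counts 2 oxidative phosphorylation genes were lower (median -0.32), and 8 fatty acid oxidation genes were lower and 2 higher (median -0.47). Atrial ion channels had 7 lower and 2 higher of 38 (9 and 2 adjusted over the list alone), with a median of -0.45 that turned to 0.27 with total counts, where 0 were lower and 5 higher (camera adjusted p = 0.000759, and adjusted p = 0.267 with an estimated correlation).

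In MI_ART versus Sham 2488 genes were higher and 1433 lower (20.3%), and 63.5% of calls were higher, against 98.5% (8032 higher, 124 lower) with total counts. The libraries of both groups did not overlap in 9321 genes (48.2%), where chance gives 10%. The number of lower genes depended on single libraries: it was 784, 799 and 642 without Sham 1, 2 and 3, 455, 774 and 659 without MI_ART 1, 2 and 3, and 2896 without MI 4, and that of higher genes was 1596 without MI_ART 1. Of the 21 panel genes 11 were higher and 0 lower, and the lower count depended on the fit. Tgfb1 (2.65-fold, adjusted p = 0.0285) did not pass without Sham 1, Sham 2, Sham 3, MI_ART 1 or MI_ART 3 (0.000585 to 0.100 over the 9 libraries left out in turn), Casp1 (2.02-fold, 0.0223) without Sham 1, Sham 2, MI_ART 1 or MI_ART 3 (0.0159 to 0.0947), and Nppb without MI_ART 1 (0.0537). Without MI 4, Gpx4 (adjusted p = 0.0156) and Ryr2 (0.00983) passed on the lower side, where total counts over all 9 libraries turned their log2 fold changes to 0.28 and 0.01, and Atp2a2 passed without MI 2 or MI 4 (0.00233 to 0.189). With the groups fitted alone Atp2a2, Ryr2 and Gpx4 were lower (adjusted p = 0.00151, 0.00968 and 0.0247). They also passed with the replicate block (0.00261, 0.0281 and 0.0274) and with MI 4 and MI_ART 3 left out together. DESeq2 called Atp2a2 lower as well (0.0226).

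The genes with the highest fold changes in MI_ART versus Sham had no counts in Sham. Apoc2 was at least 133-fold higher, Depdc1a at least 103-fold, Sirpb1b at least 78.6-fold, Marco at least 70.4-fold, Mmp8 at least 64.6-fold, Steap1 at least 52.5-fold, Crct1 at least 51.4-fold and Gdf3 at least 42.3-fold. Hpca (at least 89.5-fold on average) rested on MI_ART 1 with 14.6 CPM and did not pass without Sham 2 or Sham 3 (adjusted p from 0.00857 to 0.0576 over the 9 libraries left out in turn). Nor did Hpca pass with limma-voom (log2 7.06, adjusted p = 0.255). Cpne6 averaged at least 40.8-fold higher, with 2.34 ± 3.89 CPM. With 1 library left out Cpne6 passed only without MI 4, MI_ART 2 or MI_ART 3 (0.0220 to 0.104). Its call was also lost with limma-voom (log2 5.32, adjusted p = 0.276) and with no filter (adjusted p = 0.0646). Of the genes with the lowest fold changes, Fbxo34 fell 29.5-fold (adjusted p = 0.00536) and mt-Tl2, a mitochondrial leucine tRNA, 7.73-fold. Inmt (log2 -3.42) did not pass without MI_ART 1 (adjusted p up to 0.0603). Cdhr3 (-3.09) did not pass without Sham 1, MI_ART 1 or MI_ART 2 (up to 0.0782), and Cyp1a1 (-4.11) without Sham 1, Sham 2, Sham 3 or MI_ART 3 (up to 0.0913). Strit1 (-4.40), Helt (-3.11) and Clec18a (-3.24) passed with all 9 libraries. With 1 library left out, Strit1 passed only without MI 4 (0.00809 to 0.130) and Helt only without MI 2 or MI 4 (0.0131 to 0.144). Clec18a then passed only without MI 2, MI 3 or MI 4 (0.00101 to 0.0925). Over all alternatives the call was lost in 11 of 19 for Strit1, 10 of 19 for Helt and 8 of 19 for Clec18a. With total counts Strit1 and Helt did not pass (0.0518 and 0.0708). With 1 library left out, Cfap54 (-2.99) passed only without Sham 2, MI 2, MI 3 or MI 4 (0.0123 to 0.133). Over all alternatives the Cfap54 call was lost in 9 of 19.

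The genes called against Sham were shared between vehicle and artesunate: 2383 were higher in both, where independent lists give 467, and 1348 were lower in both, where they give 205. No gene was called in opposite directions against Sham. Across all genes the fold changes against Sham had r = 0.911, where 30 simulations of unchanged groups with the same shared Sham libraries gave 0.519, and a covariance of 2.23, where they gave 0.229. These simulated groups yield almost no calls, so their shared count of 0 is no measure of what shared controls give. The 2383 are 65.6% of the genes higher in MI, and the 1348 are 48.7% of those lower in MI, and the shared lower count depended on single libraries and on the fit. It was 748, 762 and 623 without Sham 1, 2 and 3, 438, 704 and 633 without MI_ART 1, 2 and 3, and 2426 (78.7% of those lower in MI) without MI 4, while the shared higher count was 1583 without MI_ART 1 and 3057 (84.4%) without MI 4. The shared lower count was 678 with the atrial covariate, 898 with no filter and 2234 (77.9% of those lower in MI) with the replicate block. MI 4 is the only library with title number 4, so the block gives it no weight in the group comparisons. With total counts 7663 were shared higher and 114 lower.

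Whether genes changed after infarction moved back with artesunate was asked through opposite calls and through the fold changes of all genes. Tnnt3, higher in MI versus Sham and lower in MI_ART versus MI, was the 1 gene called in opposite directions, counting both ways round, where independent lists give 0.376 and 30 simulations with shared MI libraries gave 0 on average, which unchanged groups with almost no calls yield in any case, and DESeq2 gave 74. Without MI 2 (Tnnt3 and, lower after infarction, Kcnv2) and without MI 3 there were 2 genes called in opposite directions either way round, and without any other single library there were 0. Across the 19326 genes, which are not independent replicates, the fold changes of MI_ART versus MI and MI versus Sham had r = -0.464, where shared libraries alone gave -0.486 (range -0.514 to -0.449). Their covariance was -0.531, where shared libraries alone gave -0.210 (-0.230 to -0.195). MI has 3 libraries, so it could not be divided with at least 2 on each side, and part of the excess may come from shared libraries.

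**Figure D4:**
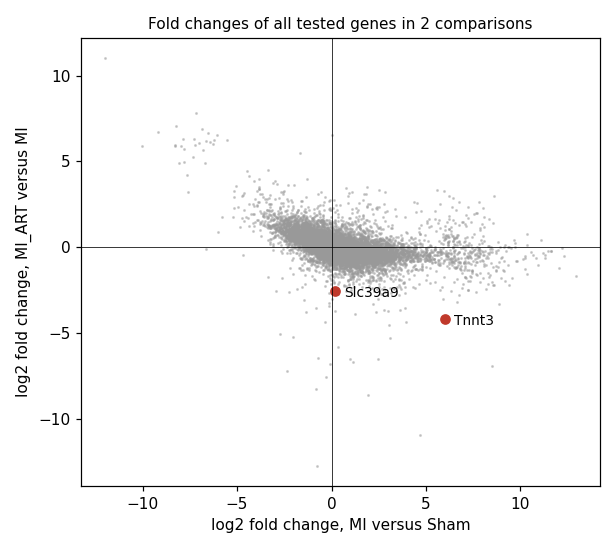
Log2 fold change of MI_ART versus MI (vertical) against MI versus Sham (horizontal) for 19326 genes, with Slc39a9 and Tnnt3 marked. The covariance is -0.531, and the fold changes of genes absent from a group depend on the prior count.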

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

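The tests on atrial transcripts in MI_ART 3 and those of skeletal muscle, atrial share and Lsp1 ratios behind the Tnnt3 and Tnni2 levels were chosen after the result was seen.

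A test of the difference between artesunate and vehicle after infarction singled out Slc39a9 (log2 -2.54, 5.83-fold lower) and Tnnt3 (log2 -4.18, 18.2-fold lower). Slc39a9 was called in 18 of 20 settings and Tnnt3 in 4 of 20. Tnni2, which stands near Tnnt3 on chromosome 7, was at 15.4, 22.2 and 44.2 CPM in MI 2, MI 3 and MI 4 and at 1.46, 4.06 and 1.44 CPM in MI_ART 1 to 3, and its fall did not pass (log2 -3.55, adjusted p = 0.455). Fast skeletal muscle in the MI samples would have raised its other transcripts, but the median log2 fold change of 8 other skeletal muscle genes was 0.0427 in MI versus Sham. They ranged from -1.15 (Atp2a1) to 2.82 (Myoz1), and none passed. Acta1, Neb and Mybpc2 stood at 10.7 CPM or more in Sham, so they can say little. Mylpf was at 0.444, 0.568 and 0.884 CPM in MI, against 0.498, 0.592 and 1.01 in Sham. These values argue against skeletal muscle as the source of the rise. In MI_ART versus MI the list of 10 skeletal muscle genes, Tnnt3 and Tnni2 among them, had a median of -0.64. A larger share of atrial muscle in MI is also argued against: Sham 1, Sham 3 and MI_ART 2 held as much Myl7 as the lowest MI library, and the lowest Tnnt3 in MI (21.8 CPM) was 7.78-fold the highest among those 3 (2.80 CPM). For reads of Lsp1, which lies between Tnni2 and Tnnt3, the rule written first rested on the fold change of Lsp1 itself in MI_ART versus MI. Its log2 value of -0.61 (SE 0.24, adjusted p = 0.709) fell between the limits for and against, so that rule did not decide. By the ratios chosen afterwards, reads in proportion to the level of Lsp1 are argued against as the whole cause. The lowest MI library's ratio to Lsp1 was 5.56-fold the highest of the other 6 libraries for Tnnt3 and 1.86-fold for Tnni2. An effect of artesunate on both genes stays open as a hypothesis.

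Libraries of one group differed in atrial transcripts, most of all in MI_ART 3. There 9 atrial-restricted genes stood at a median log2 of -2.34 against MI_ART 1 and 2, while genes of all heart muscle stood at 0.13 and ventricular genes at 0.21, which is consistent with less atrial muscle in that sample. Depth is argued against, since MI_ART 3 held 99.3% of the mean counts of the other MI_ART libraries. Myl7 ranged 4.90-fold between Sham libraries, so part of the spread arose with neither infarction nor artesunate. That range is too small to account for MI_ART 3 (1.96 CPM of Myl7, against 168 in the lowest Sham library). An effect of infarction or artesunate shared by the group is argued against as the cause in MI_ART 3. MI_ART 1 and 2 carried the same treatment label and held 173 and 803 CPM of Myl7, within the 168 to 822 CPM of the Sham libraries. An effect in the MI_ART 3 sample alone stays open. The labels give a tissue but no dissection notes, so what was cut stays open.

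Genes that changed after infarction had, as a set, opposing estimates with artesunate. For shared MI libraries as the whole cause, the covariance was -0.531 against -0.210 in simulations (lowest -0.230). These draw genes independently and so give a narrow range. They also give every group the same mean and spread per gene, although MI 4 stood apart within MI, so they are no firm limit. The correlation of -0.464 lay within the simulated -0.514 to -0.449 and does not argue against shared libraries. Without MI 4 the covariance was -0.676, against -0.378 in simulations, while the correlation, -0.453, was weaker than the simulated -0.606 (-0.626 to -0.580). With the same spread set for every group, these simulations cannot decide whether MI 4 alone was the cause. With 1 MI library in MI versus Sham and the others in MI_ART versus MI, the covariance was -0.352, -0.299 and -0.210 for MI 2, MI 3 and MI 4. The other way round it was -0.131, -0.293 and -0.436. No MI library was shared there and each value lay below 0, which argues against shared libraries as the whole cause. MI 4 was part of each of these divisions. A smaller share of infarct-responding tissue in the MI_ART samples and an effect of artesunate also stay open. For each list gene higher in MI, the log2 fold change against Sham in MI_ART was divided by that in MI. The median ratio was 0.864 in matrix (quartiles 0.809 to 0.899), 0.877 in cell cycle and 0.897 in cytokine genes. In macrophage genes the median ratio was 0.981 (quartiles 0.911 to 1.00), and the medians spanned a range of 0.117. A smaller share of tissue would act on CPM rather than on log2 values, so these ratios cannot decide.

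Splits of 6 libraries into 3 against 3 number 10, too few for a share under 0.05. In MI versus Sham 1 split gave as many genes as the real 6399, with 0 as the highest of the others, and 1 gave as many called lists as the real 36, with 32 as the highest other. In MI_ART versus MI 1 split gave as many genes as the real 2 (highest other 1), and 3 gave as many lists as the real 19 (highest other 27). In MI_ART versus Sham 1 split gave as many genes as the real 3921 (highest other 1), and 1 gave as many lists as the real 35 (highest other 32). Opposite calls reached the real 1 in 2 splits (highest other 1). Splits that mix the groups called 9 to 32 lists with 0 or 1 genes, all by camera at its preset correlation, and the source of these list calls was not tested. Each mixed split still sets most libraries of one group against most of the other. Part of the real difference thus stays in it and the rest widens the spread, so these splits are no measure of unchanged groups.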

How the results depend on the processing

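Total counts, the covariate for atrial transcripts and MI 4 and MI_ART 3 left out together were chosen after the data were seen; the cause was not tested for any value below unless stated. Of 2304 values of 116 named genes in MI versus Sham, 2248 kept direction and side of the threshold, 38 were weaker, 15 stronger and 3 reversed. In MI_ART versus MI these were 853, 18, 10 and 15 of 896, and in MI_ART versus Sham 669, 72, 14 and 8 of 763. The 18 weaker values in MI_ART versus MI belong to Tnnt3 (16 of 20 alternatives) and Slc39a9 (2 of 20). The other genes named there were not called and had no call to lose, so most kept values say little. At 3 libraries per group a 2-fold change was recovered for 8.22% to 12.7% of genes.

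Gene counts moved by over 1.5 times as follows. MI versus Sham: total counts gave 9528 higher and 644 lower, and a log2 fold change of at least 1 left 1706 lower. MI_ART versus MI: DESeq2 gave 45 higher and 40 lower, no lower gene passed with the groups compared alone, and 1 was lower with upper-quartile factors, voom, no filter, the replicate block, total counts, the covariate and both libraries left out. MI_ART versus Sham: 8032 were higher with total counts, and 952 lower with no filter, 2538 with the groups alone, 2676 with the block, 124 with total counts, 705 with the covariate and 618 with the fold change minimum, which removes genes by construction. Opposite calls were 74 with DESeq2 and 0 with upper-quartile factors, voom, no filter, the groups alone, the block, the covariate and both libraries left out. List calls were 0 in all 6 counts with an estimated correlation, fry gave 0 and 0 in MI_ART versus MI, and the block gave 15 higher lists there. The title numbers do not pair the libraries: correlations ran from -0.0354 to 0.0932 for the same number and from -0.121 to 0.108 otherwise. Number 4 occurs in MI 4 alone, so the block also takes that library out of the group comparisons.

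With each library left out, higher and lower genes ranged from 2854 to 3620 and from 1952 to 3081 in MI versus Sham, from 0 to 1 and 0 to 3 in MI_ART versus MI, and from 1596 to 3434 and 455 to 2896 in MI_ART versus Sham. Opposite calls ranged from 0 to 2. Higher and lower lists ranged from 20 to 22 and 12 to 15, from 8 to 11 and 9 to 14, and from 20 to 22 and 14 to 15.

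Reversed genes in MI versus Sham were Gpx4 (0.49), Gja1 (0.11) and Kcna5 (0.0469) with total counts. In MI_ART versus MI they were Gpx4 (0.22 with the block, 0.12 with both left out), Kcnj3 (-0.0151 with the block) and Spp1 (-0.0312 with voom, -0.36 with the block, -0.0439 with total counts). With each library left out, Casp1 ranged from -0.20 to 0.0838, Gpx4 -0.26 to 0.17, Hmox1 -0.0935 to 0.36, Kcnj3 -0.0740 to 0.97, Actc1 -0.24 to 0.10 and Spp1 -0.32 to 0.40. In MI_ART versus Sham they were Gpx4 (0.28), Gja1 (0.48), Gja5 (0.29), Kcna5 (0.45), Cacna1c (0.30) and Ryr2 (0.00551) with total counts and Gja5 (0.10) with the covariate. There Nppa ranged from -0.85 to 0.86 with each library left out.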

Other observations

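The tests of atrial share, skeletal muscle and atrial transcripts are in the part on results for a closer look; the genes and libraries given here were looked up after the data were seen, except for the fixed lists and their members.

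Clock and immediate early genes also differed between MI and Sham. Of 18 circadian genes 11 fell and 1 rose in MI versus Sham (12 and 1 adjusted over the list alone), with a median log2 fold change of -1.08, and with total counts -0.24, where 4 fell and 4 rose (camera adjusted p = 0.000160, and adjusted p = 0.147 with an estimated correlation). Hlf, Dbp and Tef, the clock-driven PAR bZIP factors, fell 5.06-fold, 3.48-fold and 2.21-fold, of which Tef did not pass with total counts (log2 -0.30, adjusted p = 0.178), and Per3 fell 3.09-fold. In MI_ART versus Sham 9 fell (10 fell and 1 rose adjusted over the list alone), with a median of -0.67 that turned to 0.07 with total counts (camera adjusted p = 0.000188, and adjusted p = 0.139 with an estimated correlation). Of 23 immediate early genes 20 rose in MI (20 adjusted over the list alone), with a median of 1.43 (camera adjusted p = 2.87e-08, and adjusted p = 0.147 with an estimated correlation), and 17 rose in MI_ART versus Sham (19 adjusted over the list alone). Egr2 rose 21.4-fold, Atf3 9.05-fold, Junb 5.73-fold and Ier3 3.08-fold in MI. The labels give no time of day for the harvest.

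Of 32 ferroptosis regulators 10 rose and 5 fell in MI versus Sham (10 and 5 adjusted over the list alone), and 10 rose and 4 fell in MI_ART versus Sham (10 and 5 adjusted over the list alone), with medians of 0.05 and -0.02, and with total counts 21 rose and 0 fell in MI (median 0.88) and 17 rose and 0 fell in MI_ART (the median turning to 0.72). Camera did not call them (adjusted p = 0.533 and 0.491). In MI versus Sham fry called them higher in 1 direction (adjusted p = 0.00277), a form that passed 38 of 57 lists there. Its mixed form gave an adjusted p of 3.72e-06 and passed 52 of 57 lists. Those that rose in MI include Slc7a11, the cystine transporter (24.1-fold), Ftl1, the ferritin light chain (6.58-fold), and Ptgs2 (5.59-fold). Of 26 NRF2 targets 10 rose and 8 fell in MI (10 and 8 adjusted over the list alone), and 15 rose and 4 fell with total counts. Of 26 genes of the integrated stress and unfolded protein responses 15 rose and 2 fell (16 and 3 adjusted over the list alone), with a median of 0.81, and 22 rose and 1 fell with total counts (camera adjusted p = 0.000182, and adjusted p = 0.147 with an estimated correlation). Of 28 interferon-stimulated genes 13 rose (13 adjusted over the list alone), with a median of 0.56, and 26 rose with total counts, with a median of 1.43 (camera adjusted p = 0.000958, and adjusted p = 0.437 with an estimated correlation). Lymphatic endothelial genes were higher in MI_ART versus MI as a list, with a median of 0.69, 0 of 7 called over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00884, and adjusted p = 0.284 with an estimated correlation). The list of mesothelial and epicardial cell genes had a median of -0.67 in that comparison, with 0 of 13 called and 0 adjusted over the list alone (camera adjusted p = 0.000649, adjusted p = 0.535 with an estimated correlation, and 0.188 without MI_ART 3). Its median difference from Sham was 0.93, 1.24 and -0.38 in MI_ART 1 to 3 and 1.33, 0.71 and 0.95 in MI 2, MI 3 and MI 4.

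Sham 1 held airway secretory transcripts: Scgb1a1 had 6664 counts there, Bpifa1 13270 and Scgb3a2 1014, and each had 0 to 8 counts in any other library. MI 4 held Bmp10 at 42.0 CPM, with at most 0.200 CPM in any other library. The fat gene Adipoq was at 48.1 CPM in MI 4, 24.8 in MI_ART 2 and 0.875 to 15.2 in the other libraries, and Cfd was at 295 CPM in MI 4, 108 in MI_ART 2, 61.7 in Sham 1 and 2.53 to 29.4 in the others. Fbxo34 was at 16.1, 7.82 and 9.54 CPM in Sham 1 to 3, at 3.37, 3.44 and 0.151 CPM in MI 2, MI 3 and MI 4, and at 0.296, 0.413 and 0.419 CPM in MI_ART 1 to 3. The nuclear gene models Gm28437, Gm28661 and Gm10925 held counts close to those of mt-Co3, mt-Co2 and mt-Atp6, between 91.7% and 104% of them in each library.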
